A study of Emberiza bruniceps with 4 samples.

How the data were processed

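Hypothalamic RNA of wild-caught red-headed buntings had been sequenced from 4 libraries, 1 for each combination of season (spring or autumn) and gonadal state (intact or castrated), and each sample was placed in its group by the group its label states. Per the labels' protocols, the tissue was ground under liquid nitrogen, RNA was taken up in Tri reagent and libraries were built for Illumina sequencing. Per the submitters' processing notes, Trimmomatic and kallisto were used, with no versions stated. The assembler and the search tool behind the protein matches, with their settings, are not given in the sources used here.

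For each library the authors deposited estimated counts per contig, which are kallisto's fractional shares of reads among similar contigs and are not normalized, together with TPM, a length-corrected share of transcripts, that the authors' tool computed from them with each contig's length and effective length. The authors also deposited a list of contig matches to collared flycatcher proteins, with an e-value, a bit score, the percent identity and the percent of the contig covered. Since kallisto shares a read among all contigs it fits, counts can move between near-identical contigs, and a gene on 1 contig can show 0 in a library for that reason.

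The 507906 contigs listed were joined to proteins by the best match with an e-value of at most 1e-05, which left 50994 contigs with counts. Estimated counts were summed over contigs with the same flycatcher protein name and rounded to whole numbers, giving 11942 names. Library size was the total over matched contigs, 40.0% (spring intact), 39.1% (autumn intact), 40.1% (spring castrated) and 41.7% (autumn castrated) of all estimated counts; the contigs without a kept match were left out. Genes with a mean of at least 1 CPM over the 4 libraries were analysed, which left 10556. CPM was scaled by TMM factors of 1.01, 1.04, 1.03 and 0.923 in the same order of libraries, computed with the trims edgeR uses (30% of ratios, 5% of levels), and log2 ratios were taken after adding 0.5 CPM.

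With 1 library per group the spread within a group cannot be measured, and the only test across libraries is the additive fit named below. Genes were called by a rule of size (2-fold), and each ratio was given an exact interval at 95% from the binomial split of its counts, which covers counting error only and is computed without the added 0.5 CPM. Reads without molecular identifiers are not independent molecules, so even this interval may be too narrow. A count of 0 allows up to 3 counts, or 0.410 (spring intact), 0.406 (autumn intact), 0.429 (spring castrated) and 0.298 CPM (autumn castrated). Numbers of genes shared by 2 pairs were set beside the product of the calls over the genes analysed. The 4 pairs of libraries compared were the seasons within each gonadal state and the gonadal states within each season.

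The files give protein names and no gene symbols. Of 957 symbols in 32 gene lists fixed before the data were examined, 668 were paired by hand with an exactly equal flycatcher protein name, and 615 of these were among the genes analysed; TF was paired with serotransferrin after its counts had been seen. A list was scored with at least 3 measured members, which left 31. Each list's median log2 ratio was placed among the medians of 10000 random lists drawn from the same 10 classes of mean CPM. Where a member had 0 counts in 1 library, the median was also taken with that member at its bound against 3 counts; this moved 8 of 124 medians, by at most 0.494. Some genes stand in more than 1 list.

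The genes named follow a rule written before the data were examined: for season and for castration up to 10 genes in each direction 2-fold apart in both pairs, ranked by the smaller counting-interval bound; for each pair the 5 in each direction with the farthest bound; up to 5 in each direction with opposite directions; and up to 4 members of each list with the largest ratios, with any member of the gonadal axis, thyroid, clock, feeding, vasotocin and stress lists. The rule asks for genes with a symbol, which was read as genes with a characterised protein name. MBP, DLK1, ADORA2A, ZBTB18, NEUROD6 and neuroligin-3 were named after their values had been seen. Some genes the rule selects are not reported here.

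Alternatives were DESeq2's median-of-ratios factors and library totals in place of TMM, no filter beyond 1 count and a mean of at least 5 CPM, an added 0.1 or 2 CPM, the authors' TPM summed per gene, matches with an e-value of at most 1e-20 and at least 70% identity, the contig with the highest mean count per gene, libraries thinned to the smallest total, and single contigs in place of genes. An additive quasi-likelihood fit of season and gonadal state in edgeR 4.0.16 (R 4.3.3) was a further alternative, with Benjamini-Hochberg adjustment; it has 1 residual degree of freedom and takes a lack of interaction as its error. Added after the data were seen were matches that cover at least 20% of the contig, contigs whose matches carry 1 protein name, random lists matched on contig length as well as mean CPM, and the castration count without 1 library in turn. The last was set beside 20 simulations of libraries with no difference. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 2-fold rule was tried on simulated counts with known folds and counting error only. It found 40.0% to 51.0% of genes with a true 2-fold difference over the 4 pairs. Of those with a 4-fold one it found 99.0% to 100%. For edgeR, counts were simulated at an assumed dispersion of 0.1, with no difference by gonadal state and no interaction. There it found 8% of 2-fold and 96% of 8-fold season differences. These shares need not hold for the real libraries.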

Results

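RNA was sequenced from the hypothalamus of red-headed buntings (Emberiza bruniceps), migratory songbirds caught in the wild, in spring and in autumn, with the gonads intact or removed. Each of the 4 groups (spring intact, autumn intact, spring castrated and autumn castrated) was represented by 1 library, so no group has a replicate, and the labels do not state how many birds a library holds. The libraries held 18155277 (spring intact), 18210588 (autumn intact), 16840270 (spring castrated) and 26213011 (autumn castrated) estimated counts. Of these, 7258655, 7122815, 6759990 and 10918843 in the same order fell on contigs matched to a flycatcher protein. The comparisons cover 10556 genes, each the sum of its matched contigs. Genes are called 2-fold apart when the log2 ratio of their CPM (counts scaled to a common library total) reaches 1 in size, and bracketed ranges are 95% intervals for counting error only. A test on the reads of 2 libraries compares those libraries, not the conditions.

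The libraries grouped by gonadal state. Across genes, which are not independent replicates, the log2 CPM of the 2 intact libraries correlated at Pearson r = 0.967 and that of the 2 castrated libraries at 0.964, against 0.875 to 0.892 for each intact library with a castrated one. Castrated and intact libraries were 2-fold apart at 2447 genes in spring and 2909 in autumn, and spring and autumn libraries at 743 genes in intact and 833 in castrated birds.

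The first question is how castrated birds differed from intact birds in either season. Many genes known from the telencephalon were lower in both castrated libraries, and many known from the hindbrain, midbrain and pituitary were higher. PPP1R1B (DARPP-32, a dopamine-regulated phosphatase inhibitor of striatal neurons) stood at 166 and 223 CPM in the spring and autumn intact libraries and at 0.715 and 0.794 CPM in the castrated ones, with log2 ratios of -7.09 (-9.48 to -6.63) in spring and -7.43 (-9.35 to -7.15) in autumn. In the other direction, HOXA3, a hindbrain patterning gene, had 357 and 319 counts in the spring and autumn castrated libraries and 0 in each intact library. Prolactin (PRL) had 481 and 826 counts in the castrated libraries against 1 and 0 in the intact ones, and somatotropin (GH1) 385 and 1872 against 1 and 0.

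In all, 1492 genes were at least 2-fold apart between castrated and intact libraries in the same direction in both seasons, 478 higher and 1014 lower, where 346 would be shared if the calls of the 2 pairs were independent. Across genes the log2 ratios of the spring and autumn pairs correlated at r = 0.71 (Spearman rho 0.68). The 2 pairs share no library. Besides PRL, GH1 and HOXA3, the genes that led the higher side were HOXA2, EN1, urotensin-2B, CGA (the alpha chain of the glycoprotein hormones), paired box protein Pax-2, the serotonin transporter SLC6A4 and POMC. SLC6A4 was higher by log2 ratios of 5.80 (5.43 to 6.63) and 5.21 (4.83 to 6.11). The leading genes on the lower side included PPP1R1B, RAS guanyl-releasing protein 1, regulator of G-protein signaling 12, the glutamate receptor GRM5, BCL11B, diacylglycerol kinase eta, interleukin-1 receptor-like 1 and the GTP-binding protein Rhes, with log2 ratios from -7.09 to -5.18 in spring and from -7.43 to -4.84 in autumn. Several of these, among them PPP1R1B, Rhes and BCL11B, are known as genes of striatal neurons.

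**Figure D1:**
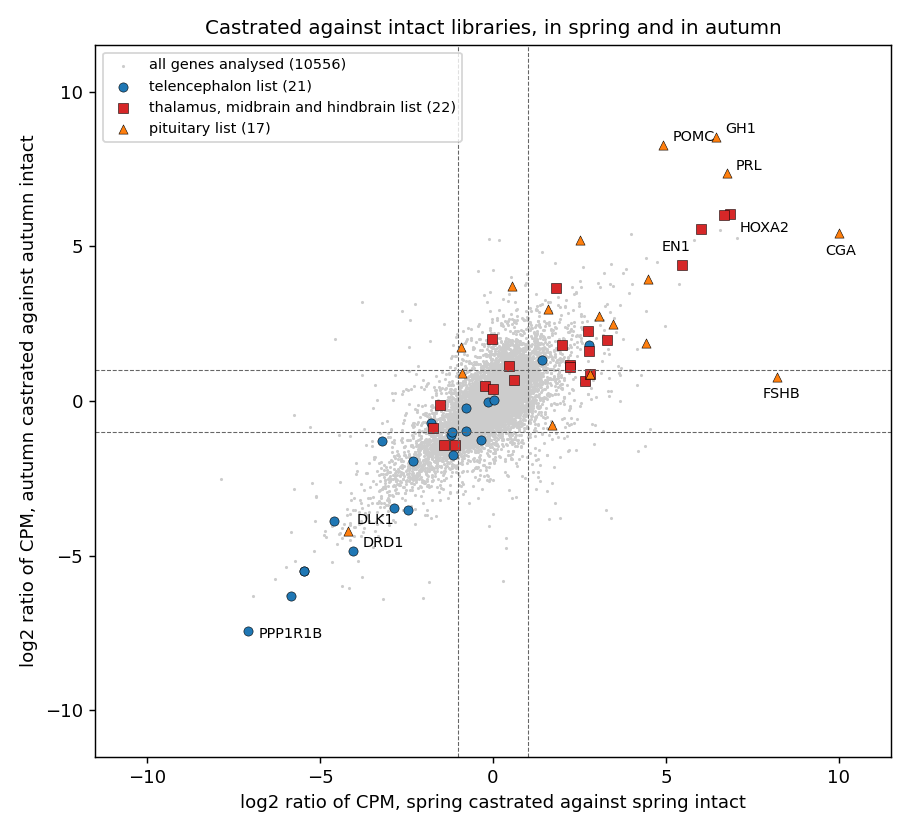
Log2 ratio of CPM, castrated against intact, in spring (horizontal axis) and in autumn (vertical axis) for the 10556 genes (grey), with 3 lists of marker genes in colour; dashed lines mark the 2-fold rule. PPP1R1B lies at the lower left and PRL, GH1, POMC and CGA at the upper right, while FSHB lies far to the right but within the 2-fold rule in autumn.

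Lists of marker genes were fixed before the data were examined. A list's median is placed among 10000 random lists of like size and mean CPM, as a description of these libraries, and stands apart when it lies in the lowest or highest 2.5%. Of the 21 measured telencephalon genes, 13 were at least 2-fold lower in both castrated libraries and 2 were higher, with medians of -1.79 in spring and -1.30 in autumn. The 22 measured genes of thalamus, midbrain and hindbrain had medians of 2.12 and 1.15, with 11 higher in both, led by HOXA2, HOXA3, EN1 and HOXD3, and 2 lower in both. For the 17 measured pituitary genes the medians were 3.08 and 2.76, with 10 higher in both castrated libraries and 1, DLK1, lower. With members at 0 counts set at their bound the pituitary medians were 3.18 and 2.83. These 6 medians all stood apart.

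Transmitter and peptide genes also differed. For these, and for the castration ratios above and below, an effect of gonadal state cannot be told apart from different pieces of tissue. Of 28 genes of GABA and glutamate transmission, 15 were at least 2-fold lower in both castrated libraries (medians -1.47 and -1.30, both apart). Among them were GRM5, the GABA-synthesising enzyme GAD2 (-4.03 and -4.06) and the NMDA receptor subunit GRIN2B (-4.05 and -3.52). The vesicular glutamate transporter SLC17A6 was higher (1.10 and 1.54). Within the 34 monoamine genes, whose medians of -0.00 and -0.29 lay within the random lists, the serotonin genes SLC6A4 and TPH2 (4.03 and 3.79) and the vesicular transporter SLC18A2 (3.76 and 4.14) were higher, and the dopamine receptors DRD1 (-4.04 and -4.85) and DRD5 (-4.65 and -5.21) were lower. The most abundant contig of DRD1 alone gave the other sign in spring (2.91). The 12 genes of the vasotocin, mesotocin and opioid list had medians of -0.77 and -1.12, both apart. Prodynorphin PDYN (-3.89 and -3.58) and the prolactin receptor PRLR (-3.64 and -3.67) were lower, and the pituitary vasotocin receptor AVPR1B, with 0 and 1 counts in the intact libraries and 90 and 139 in the castrated ones, was higher.

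Among 39 feeding and energy balance genes (medians -0.39 and -0.52, both apart), 9 were lower in both castrated libraries, among them NPY (-3.09 and -2.36) and IGF1R (-3.73 and -2.89), and 5 were higher, among them ADCYAP1 (2.07 and 2.02), somatostatin SST (1.26 and 2.09) and POMC. Clock genes were on balance lower: of 21 measured, 6 were at least 2-fold lower in both and 0 higher, 17 were below 0 in both and 1 above 0 in both (medians -0.54 and -0.82, both apart), with CLOCK at -2.53 and -1.81, TEF at -2.75 and -1.86 and PER3 at -3.46 (-10.85 to -2.97, on 1 count in the spring castrated library) and -1.87. On the gonadal axis list (26 genes, medians 0.25 and 0.07, within the random lists), aromatase CYP19A1, which makes oestradiol from androgens, was at -2.33 in each season, the progesterone receptor PGR was lower (-1.02 and -0.86), and the activin and inhibin subunits INHBA (1.03 and 1.42) and INHBB (1.12 and 1.08) were higher. Markers of hypothalamic regions (20 genes) went both ways, with 6 higher and 7 lower in both, and medians of -0.19 and 0.23 within the random lists. LHX8 (-5.85, -9.23 to -5.39, and -4.23), LHX6 (-4.44 and -4.29) and NKX2-1 (-3.03 and -3.36) were lower. The most abundant contig of LHX6 alone gave 0.00 in autumn.

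Genes of myelin and of energy metabolism were on balance higher in the castrated libraries. Of 21 oligodendrocyte and myelin genes, 9 were at least 2-fold higher in both and 0 lower (medians 0.81 and 1.38, both apart), with myelin basic protein MBP, named after its values were seen as the best known of them, at 1.23 and 1.70. The 39 nuclear-encoded genes of oxidative phosphorylation had medians of 0.57 and 1.25, both apart, with 2 at least 2-fold higher in both and 37 above 0 in both. Medians also stood apart on the higher side in both seasons for 20 genes of glycolysis and lactate (0.56 and 0.61, with LDHB at 1.29 and 1.58 and ENO1 at 1.27 and 1.76), 24 genes of heat shock and protein folding (0.48 and 0.50, with the small chaperones HSPB1 at 2.09 and 3.08 and HSPB8 at 1.89 and 3.09) and 35 genes of lipid metabolism (0.46 and 0.40, with the sterol enzyme LSS at 1.36 and 1.54). Across genes the castration ratios went down with contig length (Spearman rho -0.25 in spring and -0.27 in autumn, against 0.04 and 0.09 for the seasons in intact and castrated birds). The medians of these 5 lists also stood apart among random lists matched on contig length as well. The 14 neuronal genes had medians of 0.36, within the random lists, and 0.75, apart, with the neurofilament genes NEFM (3.09 and 2.46) and NEFL (1.67 and 1.02) higher in both.

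**Figure D2:**
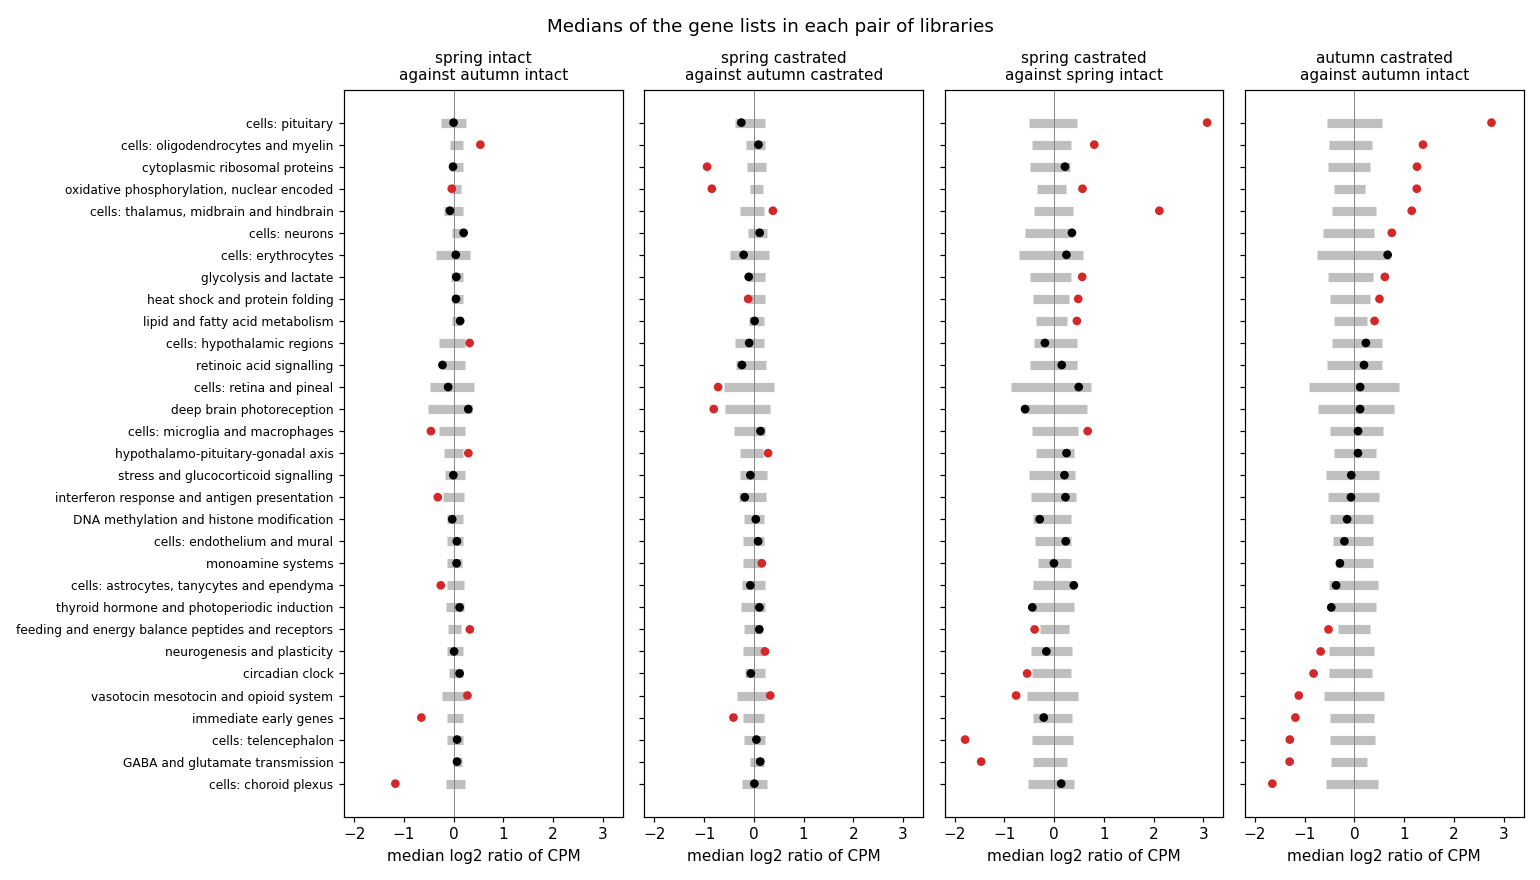
Median log2 ratio of CPM of 31 gene lists (dots, red where the median stands apart) in each of the 4 pairs of libraries, over the middle 95% of 10000 random lists of like size and mean CPM (grey bars). Pituitary genes reached 3.08 and 2.76 in the castrated against the intact libraries and telencephalon genes -1.79 and -1.30.

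Some lists stood apart in 1 season's pair only, and the difference between the seasons was not tested. In spring alone, 19 genes of microglia and macrophages were higher in the castrated library (median 0.67, with CYBB at 1.74, 0.89 to 4.46, and CD74 at 1.67, 1.57 to 1.78), against 0.07 in autumn. In autumn alone, 20 ribosomal protein genes were higher (1.26, against 0.22 in spring), and 3 lists were lower. The first was 23 immediate early genes (-1.19, against -0.21), the second 20 genes of neurogenesis and plasticity (-0.68, against -0.16) and the third 14 choroid plexus genes (-1.65, against 0.14). DCX, a gene of young neurons, was at -4.13 in spring and -3.66 in autumn. Among the genes farthest apart in 1 pair, multiple PDZ domain protein had 2056 counts in the spring intact and 5 in the spring castrated library. In autumn they included calcium-dependent secretion activator 2 (301 and 0 counts), alpha-2,8-sialyltransferase 8F (209 and 0), palmitoyltransferase ZDHHC2 (203 and 0) and potassium voltage-gated channel subfamily KQT member 3 (430 and 2), each lower in the castrated library. In the autumn pair the intact library held 7633 CPM of transthyretin (TTR), the thyroid hormone carrier made by the choroid plexus, against 1751 CPM in the castrated one.

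Genes at least 2-fold apart between castrated and intact libraries in opposite directions in the 2 seasons numbered 63, where independent calls would give 328. Of these, 43 were higher in the castrated library in spring and lower in autumn, and 20 the reverse. The count lay between 27 and 248 under the alternatives at the level of genes. These genes included TTR (1.75 in spring, -2.12 in autumn), chondroadherin (3.41 and -3.80) and the orexigenic neuropeptide QRFP, which had 47 counts in the spring intact, 2 in the autumn intact, 0 in the spring castrated and 67 in the autumn castrated library. The iodothyronine deiodinase DIO2, which activates thyroid hormone, had log2 ratios of 1.30 (0.99 to 1.67) in spring and -0.77 (-1.07 to -0.51) in autumn. The thyroid hormone and photoperiod list (19 genes) had medians of -0.44 and -0.47, within the random lists. In both seasons 2 of them, CGA and TSHB (0 counts in each intact library, 7 and 35 in the castrated ones), were at least 2-fold higher and 4 were lower, among them TEF and HLF (147 and 135 CPM in the intact, 33.9 and 23.5 in the castrated libraries).

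The second question is how spring birds differed from autumn birds. Season also cannot be told apart from different pieces of tissue, since some marker lists stood apart between seasons. Between the intact libraries the choroid plexus median was -1.17 and that of hypothalamic regions 0.32. Between the castrated ones the median for thalamus, midbrain and hindbrain was 0.38. The telencephalon and pituitary medians lay within the random lists in both season pairs. The receptors for progesterone and oestrogen were higher in the spring libraries, short of 2-fold except for PGR in intact birds. The progesterone receptor PGR was higher by log2 ratios of 1.02 (0.64 to 1.48) in intact and 0.86 (0.37 to 1.47) in castrated birds, the oestrogen receptor ESR2 by 0.84 (0.47 to 1.26) and 0.88 (0.44 to 1.44), and ESR1 by 0.91 (0.53 to 1.37) and 0.63 (0.21 to 1.13). Of 26 gonadal axis genes, 18 were above 0 in both pairs and 1 below 0 in both, with medians of 0.30 and 0.29 that both stood apart, though 0 of them reached 2-fold in both pairs. GNRH1, the releasing hormone at the head of the axis, was at -1.63 (-3.03 to -0.94) in intact birds and 2.07 (1.54 to 6.77) in castrated birds, on 42 counts or fewer in each library.

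Immediate early genes were on balance lower in the spring libraries, and so were a few genes of antigen presentation. Class I histocompatibility antigen, F10 alpha chain-like, summed over 44 contigs of a family whose members share sequence and so uncertain, was at -1.52 in intact and -1.42 in castrated birds. Its partner beta-2-microglobulin (B2M) was at -1.36 (-1.50 to -1.24) and -0.96 (-1.09 to -0.84), the transcription factor IRF1 at -1.08 and -1.17, and gamma-interferon-inducible lysosomal thiol reductase at -2.16 and -1.59. Over the 17 measured interferon and antigen presentation genes the medians were -0.32, apart, and -0.18, within the random lists, and 1 gene, IRF1, was at least 2-fold lower in both pairs. The 23 immediate early genes, which are induced within minutes by neuronal activity, had medians of -0.65 and -0.41, both apart, with 13 below 0 in both pairs and 3, NR4A3, NR4A1 and FOSL2, at least 2-fold lower in both. NR4A3 was at -3.04 (-3.59 to -2.70) and -1.12 (-1.73 to -0.66), NR4A1 at -2.46 and -1.11, FOSL2 at -1.35 and -1.06, and FOS at -2.32 (-2.50 to -2.17) and -0.47 (-0.62 to -0.32). The same list was lower in the autumn castrated than in the autumn intact library (-1.19). In intact birds the choroid plexus (-1.17), astrocyte, tanycyte and ependyma (-0.26), and microglia (-0.46) lists also had lower medians in spring. In castrated birds these medians were 0.01, -0.07 and 0.13, within the random lists.

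Between seasons, 92 genes were at least 2-fold apart in the same direction in both gonadal states, 25 higher and 67 lower in spring, where independent calls would give 32.3, and 72 were apart in opposite directions, where they would give 26.3. The same-direction count was 40 with 2 CPM added, 51 with a mean of at least 5 CPM, 283 with the most abundant contig of each gene and 312 with TPM, where 305 genes were in opposite directions. Across genes the ratios of the intact and castrated pairs correlated at r = 0.05 (rho 0.06). The leading genes on the higher side were beta-1,4-galactosyltransferase 2, charged multivesicular body protein 2a, symplekin, ribonuclease 3, pumilio homolog 3, transcription intermediary factor 1-beta, the histamine H1 receptor, E3 ubiquitin-protein ligase MIB1, importin subunit alpha-6 and transcription elongation factor A N-terminal and central domain-containing protein 2. The lower side was led by SAFB-like transcription modulator (0 and 389 counts in spring and autumn intact, 20 and 625 in spring and autumn castrated), septin-10, coiled-coil domain-containing protein 81-like, ubiquitin-associated protein 1-like, magnesium transporter protein 1, T-complex protein 1 subunit alpha, calcium/calmodulin-dependent protein kinase type IV, 39S ribosomal protein L34 of mitochondria, the class I antigen and the thiol reductase. Several leading genes on either side, among them ribonuclease 3, MIB1, SAFB-like transcription modulator and septin-10, had 0 counts in at least 1 library. Reads shared among similar contigs can also give a 0, which was not tested. The same holds for genes at 0 counts named below. With 1 residual degree of freedom, edgeR's quasi-likelihood fit of season and gonadal state together called 0 genes for season at an adjusted p under 0.05 (531 at an unadjusted p under 0.05) and 2374 for gonadal state.

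**Figure D3:**
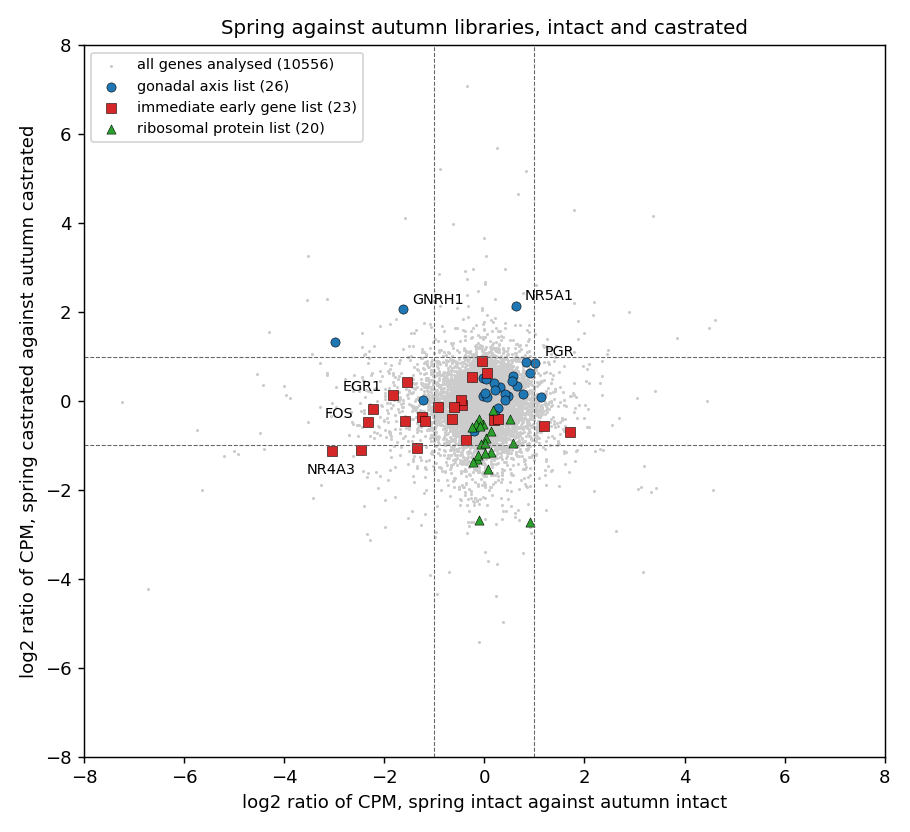
Log2 ratio of CPM, spring against autumn, in intact (horizontal axis) and castrated birds (vertical axis) for the 10556 genes (grey), with 3 gene lists in colour; dashed lines mark the 2-fold rule. Most gonadal axis genes lie a little above 0 on both axes, NR4A3 lies at the lower left, and the ribosomal protein genes lie below 0 on the vertical axis, most of them near 0 on the horizontal axis.

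In intact birds 743 genes were 2-fold apart between seasons, 269 higher and 474 lower in spring, with 423 to 1682 under the alternatives at the level of genes. Genes of the choroid plexus were on balance higher in the autumn intact library, with 7 of 14 at least 2-fold lower in spring, 0 higher and 3 above 0. TTR stood at 238 CPM in spring and 7633 CPM in autumn, the potassium channel KCNJ13 at -5.74 (-7.66 to -5.28), SLC13A4 at -3.52 and LMX1A at -3.08 (-10.50 to -2.59, on 1 count in spring), and the list's median was -1.17, apart. Serotransferrin (TF) was at 7489 CPM in that library against 353 in the spring intact one, and chondroadherin at 567 against 3.28 CPM. Of 19 astrocyte, tanycyte and ependyma genes (median -0.26, apart), 4 were at least 2-fold lower in spring, FOXJ1 (-1.60), RSPH1 (-1.54), DNAH9 (-1.42) and SPARCL1 (-1.02). Microglia and macrophage genes had a median of -0.46, apart, led by TIMD4 (-2.31) and CD74 (-1.91). Feeding genes were on balance higher in spring (median 0.33, apart), with GHSR at 1.38 and galanin GAL at 1.21, while AGRP, the peptide that drives feeding, was at -1.98 and NMU at -3.44. Oligodendrocyte genes (0.54), markers of hypothalamic regions (0.32) and the vasotocin and opioid list (0.28) also stood apart on the higher side. DIO2 was at -1.19 (-1.57 to -0.89), while between the castrated libraries its ratio had the other sign, higher in spring. Ribonuclease 3, early endosome antigen 1, MIB1, protein TANC2 and the pituitary transcription factor POU1F1, with 86, 83, 79, 49 and 35 counts in spring and 0 in autumn, led the higher side, and chondroadherin, SAFB-like transcription modulator, calcium/calmodulin-dependent protein kinase type IV, KCNJ13 and TTR the lower one. Of these, ribonuclease 3 and MIB1 were also higher in spring in castrated birds, while early endosome antigen 1 went the other way there (0 counts in spring, 15 in autumn).

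In castrated birds 833 genes were 2-fold apart between seasons, 262 higher and 571 lower in spring, with 511 to 1737 under the alternatives at the level of genes. With library totals in place of scaling factors 410 of 821 were higher, and castrated against intact birds in autumn then gave 1006 of 3011 higher in place of 1300 of 2909. Library totals moved the median ratio of all genes by 0.16 and -0.16 in these pairs. In the autumn castrated library 14.8% of the matched counts lay on a single contig matched to neuroligin-3, against 1.35% to 3.55% in the others. FSHB and CGA were higher in spring: FSHB, the beta chain of follicle-stimulating hormone, had 148 CPM in the spring castrated library against 0.596 in the autumn castrated one (7.08, 6.83 to 9.41), and CGA 520 against 32.6 CPM (3.98, 3.83 to 4.16). The matches covered 16.4% (FSHB) and 13.2% (CGA) of their contigs, so neither gene is measured where a cover of at least 20% is asked. The same holds for 12 other genes named in the paragraphs on season and castration, whose identity is likewise less certain. These are TTR (15.5%), POU1F1 (14.6%), AGRP, GAD2, NEFM, RBP3, QRFP, Pax-2, septin-10, magnesium transporter protein 1, ubiquitin-associated protein 1-like and transcription elongation factor A N-terminal and central domain-containing protein 2. TSHB, the thyrotropin partner of CGA, was at -1.40 (-3.21 to -0.60). PRL, GH1 and POMC were lower in spring, with PRL at -0.25 (-0.42 to -0.09), GH1 at -1.75 (-1.92 to -1.60) and POMC at -1.13 (-1.27 to -1.01), and the pituitary list's median of -0.25 lay within the random lists. Ribosomal protein genes were lower in spring, with a median of -0.94 over 20 genes, apart, 8 of them at least 2-fold lower, led by RPLP1 (-2.71) and RPL37A (-2.67). So were genes of oxidative phosphorylation, with a median of -0.85 over 39 genes, apart, 13 at least 2-fold lower, led by NDUFB6 (-2.71) and COX7C (-2.06). The same lists had medians of -0.01, within the random lists, and -0.04, apart, between the intact libraries, the latter within the random lists when these were matched on contig length as well. The gap between contig length and effective length, which follows fragment length, was 211 bases in the autumn castrated library and 261 to 266 in the others. Besides FSHB, the higher side was led by ZDHHC2, calcium-dependent secretion activator 2, potassium voltage-gated channel subfamily H member 6 (1000 and 23 counts in spring and autumn) and alpha-2,8-sialyltransferase 8F. The lower side was led by synaptic vesicle glycoprotein 2B (0 and 210 counts), multiple PDZ domain protein (5 and 379), the alpha subunit of methylcrotonoyl-CoA carboxylase (0 and 101), heat shock protein 30C-like (34 and 1085) and SAFB-like transcription modulator (20 and 625).

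Smaller shifts between the castrated libraries included higher medians in spring for markers of thalamus, midbrain and hindbrain (0.38), the vasotocin and opioid list (0.33), neurogenesis genes (0.22) and monoamine genes (0.16), all apart. Lower medians, also apart, were found for heat shock genes (-0.12, but 0.05 with library totals, and no longer apart among random lists matched on contig length as well), 11 genes of deep brain photoreception (-0.81) and 7 retina and pineal genes (-0.72, with RBP3 at -1.25). Among the photoreception genes PDE6B was at 2.29 (1.76 to 4.57) and the melanopsin OPN4 at -1.08 (-2.72 to -0.22), whose sign turned (0.33) with its most abundant contig alone and (0.02) with matches that cover at least 20% of the contig. The medians for monoamine and neurogenesis genes were no longer apart under 8 of the 13 alternatives each. In all, 52 of 124 list medians stood apart, where 6.2 would be expected if every list were a random draw of unrelated genes. Genes of a list may vary together, some genes stand in several lists, and some pairs share a library. So 6.2 is not an estimate of what chance differences between single libraries would give. For 6 of the 31 lists (DNA methylation and histone modification, endothelium and mural cells, erythrocytes, retinoic acid signalling, stress and glucocorticoid signalling, and the thyroid and photoperiod list) no median stood apart, the values lying between -0.47 and 0.67. Medians not given above for the other lists lay within the random lists. The list of mitochondrially encoded genes had no gene among those analysed.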

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

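Several tests in this part were chosen only after the result was seen. They are those on the 20% cover of contigs, on the telencephalon list, on gonadal state and on random lists matched on contig length. The same holds for those on sequencing depth in the other libraries, on PRL, GH1 and POMC, and on NR5A1. The test on Hox genes outside the fixed lists was made after HOXA2, HOXA3 and HOXD3 had been seen.

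The genes in opposite directions under castration were singled out because the sign differed between seasons, and the difference itself was not tested. Log2 ratios in spring and autumn were 3.26 and -3.53 for MKL/myocardin-like protein 1, 3.41 and -3.80 for chondroadherin, 1.75 and -2.12 for transthyretin (match covering 15.5% of its contigs), 1.62 and -3.82 for potassium voltage-gated channel subfamily H member 6, and 1.93 and -3.78 for vezatin. On the other side they were -3.79 and 3.21 for QRFP, -2.63 and 2.92 for mannose-1-phosphate guanyltransferase beta, -2.25 and 3.14 for spindle assembly abnormal protein 6 homolog, -2.41 and 2.62 for gamma-aminobutyric acid receptor subunit gamma-3, and -4.57 and 1.99 for early endosome antigen 1. MKL/myocardin-like protein 1, vezatin, QRFP, the guanyltransferase, the receptor subunit and the endosome antigen had 0 counts in at least 1 library, so their ratios depend on the added 0.5 CPM.

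Contigs without a kept match carried 60.02% (spring intact), 60.9% (autumn intact), 59.9% (spring castrated) and 58.3% (autumn castrated) of the estimated counts, a signal outside the comparisons that was not analysed.

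The 1492 genes apart between castrated and intact libraries in both seasons include markers of brain regions and of the pituitary. Abundant contigs with a short match are argued against as the cause, since 1380 genes were counted when matches had to cover at least 20% of the contig, and a trend with contig length too, since 1373 were counted after it was taken off. Different pieces of tissue around the hypothalamus may account for many of them: 2 of 2 measured Hox genes outside the fixed lists (Hox-A1 and Hox-D4, too few to weigh much, and tested after HOXA2, HOXA3 and HOXD3 had been seen) were at least 2-fold higher in both castrated libraries, and 13 of 21 telencephalon genes were lower, although ADORA2A (log2 ratios -0.15 and -0.04, on a match covering 15.4% of its contig and so of uncertain identity) and the abundant ZBTB18 (0.03 and 0.02) were level and NEUROD6 was higher. Gonadal state acting within the hypothalamus cannot be told apart from this, because 0 of the 2 pairs had telencephalon, hindbrain and pituitary lists within the random lists.

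Ribosomal protein and oxidative phosphorylation genes were higher in the autumn castrated than in the spring castrated library. Each list's median stayed at percentile 0 among random lists matched on contig length and mean CPM. This argues against shorter fragments in the autumn library, which favour short transcripts, as the whole cause only where contig length follows transcript length. Assembled contigs can be pieces of longer transcripts, so an effect of fragment length stays possible. Comparison with the other libraries cannot tell deeper sequencing of the autumn library apart from its other traits. That is because 0 of the other 3 libraries had at least 80% of its counts. Thinning every library to the smallest total takes the difference in depth away. Over all lists and pairs, 119 of 124 medians then kept their place among the random lists, 2 came to stand apart and 3 no longer did. Season in castrated birds, or another trait of that library such as RNA quality, stays open and untested, because only 1 library of each kind exists here.

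FSHB and CGA were far higher in the spring castrated than in the autumn castrated library. Their matches cover 16.4% and 13.2% of their contigs, below the 20% asked for in an alternative, so their identity is less certain. Whether the spring library held more pituitary tissue cannot be decided from these genes. PRL, GH1 and POMC, chosen after the result was seen, had a median log2 ratio of -1.13. They are hormone genes whose expression may itself differ by season, so they cannot stand for the amount of tissue. Of the 17 measured pituitary genes, 4 were at least 2-fold higher in spring and 4 lower. Their median of -0.25 lay within the random lists. A larger share of gonadotroph cells in the spring piece may contribute: NR5A1, a gene of gonadotrophs, had a log2 ratio of 2.14, but it is also made in the ventromedial hypothalamus, so the 2 sources cannot be told apart. A seasonal difference in gonadotropin expression of castrated birds stays open and was not tested.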

How the results depend on the processing

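Alternatives chosen after the data were seen were the 20% cover of the contig, contigs whose matches carry 1 protein name, random lists matched on contig length as well, and the counts without 1 library. A change of sign was counted only for list medians that stood apart and named genes' ratios of at least 2-fold at the settings used above. Of the list medians under 13 alternatives, 1531 kept their place among the random lists. A further 31 came to stand apart, 49 no longer did and 1 changed sign. Of the named genes' ratios 8210 kept their side of the 2-fold rule, 103 crossed to 2-fold, 148 fell short of it and 15 changed sign. The castration count in the same direction lay between 1204 and 1773 under the gene-level alternatives, and 1711 (autumn castrated left out) to 2126 (spring castrated left out) without 1 library. The latter pairs share a library, so part of their agreement may come from it: simulated libraries with no difference gave 2.55 to 7.35 with counting error only and 375 to 401 at an assumed dispersion of 0.1, and independent calls would give 309 to 417. With random lists matched on contig length as well, 50 list medians stood apart, all of them among the 52. Depth limits genes of few counts, since 1 count was worth 0.0992 to 0.143 CPM.

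In the order of spring against autumn in intact birds, the same in castrated birds, both season pairs in the same direction, both in opposite directions, and castration in opposite directions, the counts were 423, 527, 51, 36 and 27 with a mean of at least 5 CPM, where fewer genes are tested. They were 434, 511, 40, 33 and 27 with 2 CPM added, 1591, 1708, 312, 305 and 248 with TPM, and 1682, 1737, 283, 277 and 234 with the contig of highest mean count. With 0.1 CPM added, 124 genes were in opposite directions between seasons. Single contigs, which are more numerous than genes, gave 9109, 9316, 2101, 2015 and 1940 in the same order, 13096 and 14013 for castration in spring and autumn, and 6056 for castration in the same direction. edgeR gave 0 for season and 2374 for castration.

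Among list medians that stood apart and named genes' ratios of at least 2-fold, these signs changed, the cause of which was not tested. With library totals, the heat shock median between castrated libraries was 0.050. With TPM, spring against autumn in intact birds gave -0.030 for ASPA and -0.28 for JUND, and castrated against intact in spring 0.65 for class I histocompatibility antigen, F10 alpha chain-like, and 0.072 for JUND. With the contig of highest mean count, castrated against intact in spring gave 2.91 for DRD1, -1.28 for NMU, 0.17 for PER2 and -0.49 for TPH1, and in autumn 0.00 for LHX6; spring against autumn gave -4.31 for GLP1R in intact birds and 0.33 for OPN4 and -1.02 for NMU in castrated birds. With 20% cover, OPN4 between castrated libraries was at 0.022 and JUND at -0.61 between intact libraries and 0.40 for castration in spring.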

Other observations

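POU1F1, the transcription factor of pituitary somatotrophs and lactotrophs, measured on 1 contig of which the match covers 14.6%, had 35 counts in the spring intact and 0 in the autumn intact library, while PRL and GH1 had 1 and 0 counts each and POMC 18 and 1. In the castrated libraries POU1F1 had 51 and 62 counts.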
